A study of Trichodesmium erythraeum IMS101 with 6 samples.

How the data were processed

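Cytosine methylation was measured by whole-genome bisulfite sequencing in Trichodesmium erythraeum IMS101, a filamentous marine cyanobacterium that fixes nitrogen. Bisulfite turns unmethylated cytosines into uracil, so the share of reads that still carry a cytosine at a position is its methylation level. Per the labels, 6 libraries came from 3 culture media, with 2 libraries per medium, and the cells were filtered as biological replicates at midday. Libraries were made with the NEXTflex Bisulfite-Seq kit and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.32 and BSMAP, with no role or order for either; the genome build, the coverage filter, the caller and the authors' test are not given in the sources used here.

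The authors deposited 2 tables. The site list gives 15652 cytosines, each with a position, a strand, a sequence context, a full or hemi state and a methylation fraction; per the file headers these are levels from 0 to 1, and the libraries behind each level are not given in the sources used here. The lowest fraction listed is 20%, so a minimum had been applied before deposit. The differential table gives, per the file headers, the methylation fraction of each of the 6 libraries at 1090 cytosines that the authors had selected as differing. All fractions were multiplied by 100 and are printed as percent. Neither table gives read counts or coverage, so the depth is unknown, no counting interval could be attached to a level, and no coverage minimum could be set.

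The tests, thresholds and alternatives were fixed before the data were examined, including which test to use if only fractions were given. That test was limma 3.58.1 in R 4.3.3 on arcsine square-root transformed fractions, with all 6 libraries in a single fit, so that the groups shared an estimate of the spread. A site was called at a Benjamini-Hochberg adjusted p under 0.01 and a difference between group means of at least 33 percentage points, thresholds that follow the name of the authors' table. Replicate numbers were not used as a block. The group means of library averages were compared with an exact two-sided permutation test. On simulated levels with a 40-point change at 200 of the 1090 sites, both thresholds together recovered 91.0% of the changed sites for iron-limited against replete, 91.5% for co-limited against replete and 90.5% for co-limited against iron-limited, with 0 unchanged sites called. With a 20-point change, the adjusted p alone recovered 10.0%, 0% and 1.0% of the changed sites in the same order. In the data nearly all sites differed rather than 200, so the adjusted p is less strict and these shares do not give the power there. For iron-limited against replete, 350 of the 1090 sites passed the adjusted p, and the median difference over all sites was 17.0 points.

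Because the table had been selected on these same libraries, counts of calls describe the selected sites and are not independent evidence that methylation differed or in which direction. At 208 sites at least 1 library was listed at exactly 0, and 206 of them were at 0 in both replete libraries. The means and calls were therefore repeated on the 882 sites above 0 in every library, and with the zeros set to 20%; these alternatives were added after seeing the data.

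Genes were taken from a RefSeq gene table of assembly ASM1426v1, which lists 5449 genes, 743 of them (13.6%) with a symbol; the others are named by locus tag. The gene table holds no strand and no product names, so the windows upstream of start codons were replaced by windows of 100 and 300 bases on either side of a gene, and list membership rests on symbols alone. Since no source used here names the build of the methylation files, the match was checked on the data. The share of listed cytosines inside coding genes was 76.5% with the positions as given and 61.0% and 61.4% with positions moved by 1000 bases down or up. The position within codons was uneven in the same sense in all 10 windows along the chromosome for each of the 3 main contexts on each strand. Positions are printed as the authors' tables give them. A genome sequence was not used here, so sequence motifs and a background of all cytosines were not analysed.

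Cytosines were also grouped by where the listed cytosine of the opposite strand lies, a grouping chosen after seeing the data. Adjacent CpG pairs have the partner 1 base away, as in a symmetrically methylated CpG. Spaced CpG pairs have a CpG partner 5 bases away, the spacing of the outer cytosines of CGNNCG. CCG pairs have a CCG cytosine on a strand and a CpG cytosine 2 bases away on the other, and CXG pairs have CXG cytosines on neighbouring bases. Intervals for shares of sites are exact binomial intervals at 95% and cover counting error only.

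The 12 gene lists fixed beforehand were nitrogen fixation; iron acquisition, storage and iron stress; phosphorus acquisition and storage; photosystems and photosynthetic electron transport; phycobilisome; carbon fixation and concentration; gas vesicle; transposases and mobile elements; DNA methylation and restriction; signal transduction and transcription regulation; toxin-antitoxin; and ribosome. Each was tested with Fisher's exact test, two-sided, on genes with a called site against genes with a tested site, counting the gene body and 100 bases either side, with Benjamini-Hochberg adjustment over the lists. The same test on genes with a site in the differential table against genes with any listed site was added after seeing the data. The rule for named sites, also fixed beforehand, took per comparison the 10 called sites with the largest rise and the 10 with the largest fall in the difference of group means, ties broken by position, where both libraries of a group lay on the same side of both libraries of the other. It added every called site in or near a gene of the nitrogen fixation, iron and phosphorus lists, up to 5 per list by size. Other genes named were chosen after their values were seen, which is stated where it applies. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for everything outside limma. Other alternatives tried were the replicate block, untransformed fractions, differences of 25 points or of any size, an adjusted p under 0.05, only the 4 libraries compared, each library left out in turn, medians over sites, other gene windows and lists matched on gene length.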

Results

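Trichodesmium erythraeum IMS101, a colony-forming cyanobacterium that supplies fixed nitrogen to warm, nutrient-poor seas, was grown at 380 µatm CO2 under 3 nutrient supplies, with 2 bisulfite libraries each. Replete cultures received 10 µM phosphate and 250 nM iron. Co-limited cultures had been kept at 0.25 µM phosphate and 10 nM iron for about 1 year, after about 7 years in replete medium. Iron-limited cultures were made from the co-limited ones by giving back 10 µM phosphate while iron stayed at 10 nM, and were sampled about 2 months later. The comparisons therefore ask how methylation differs after long co-limitation, and which part of that difference is present once phosphate has been restored. Below, a rise means a higher level in the first-named medium of a comparison than in the other, not a change over time. The deposited values are methylation fractions without read counts, so the depth behind each level is unknown.

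The site list describes a genome with many nearly fully methylated cytosines and a second, partly methylated group. Of 15652 listed cytosines, 15134 were listed as methylated on both strands (full) and 518 on a single strand (hemi), and 7826 lay on each strand. CpG cytosines made up 75.1% (95% interval 74.4 to 75.8) with a median level of 73.9%. The 1972 CXG and 1886 CCG cytosines had median levels of 95.5% and 94.2%. The 41 CHH cytosines were all hemi-methylated and had a median of 34.2%.

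Grouping by strand partner separated the CpG cytosines further. Cytosines in CXG pairs and CCG pairs were methylated at medians of 95.5% and 94.4%, and 99.3% and 93.5% of them reached 90%. The 4783 cytosines of adjacent CpG pairs had a median of 72.6%, with 23.5% of them at 90% or more. The 4678 cytosines of spaced CpG pairs had a median of 66.1%, and 1.45% of them reached 90%. Levels on the opposite strands correlated across adjacent pairs (Pearson r = 0.935 over 2381 pairs) and spaced pairs (r = 0.959 over 2328 pairs). The correlation was lower across the nearly fully methylated CCG pairs (r = 0.369, Spearman's rho 0.147, over 1877 pairs) and CXG pairs (r = 0.138, rho -0.0198, over 978 pairs). The strands nonetheless lay closest there, with median absolute differences of 1.47 points in CCG and 1.01 points in CXG pairs. In adjacent and spaced pairs these were 4.35 and 3.32 points. Pairs within a genome are not independent replicates. The 481 cytosines with no listed partner had a median of 25.8%.

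**Figure D1:**
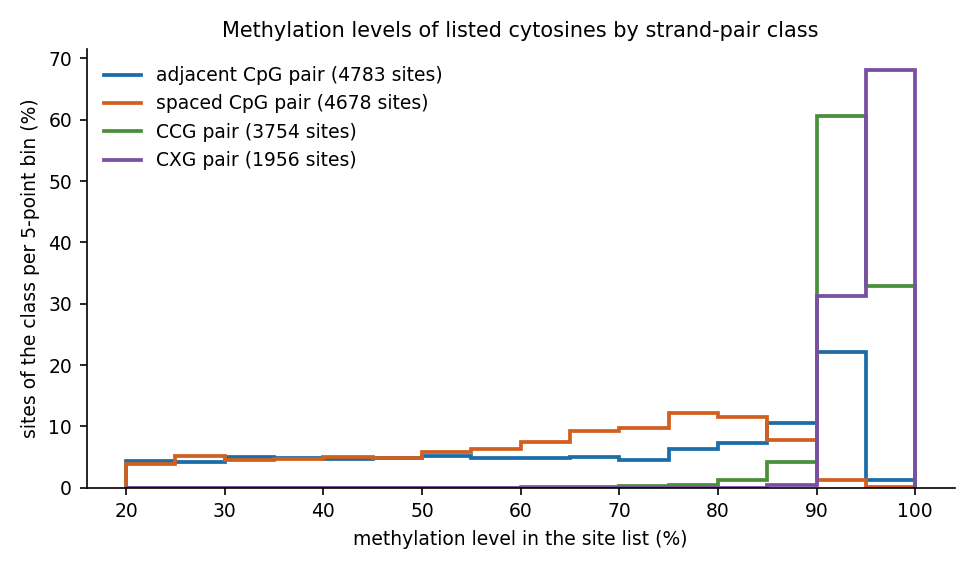
Share of listed cytosines (vertical axis, percent of the class) in 5-point bins of the deposited methylation level (horizontal axis, percent) for the 4 strand-pair classes, 1 line per class. CCG and CXG pairs pile up above 90%, while adjacent and spaced CpG pairs spread from 20% upward with medians of 72.6% and 66.1%.

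Most methylated cytosines lay in genes. Of the site list, 80.3% (95% interval 79.7 to 81.0) fell in a gene body and a further 5.46% within 100 bases of a gene. Spaced CpG pairs were in gene bodies less often, at 70.9% (69.6 to 72.2), than adjacent CpG pairs at 84.5% (83.5 to 85.5), CCG pairs at 84.1% (82.9 to 85.3) and CXG pairs at 86.5% (84.9 to 88.0). Listed cytosines fell in the bodies of 2950 genes.

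The sites that the authors selected as differing were almost all CpG. The table held 1085 CpG, 4 CHH and 1 CCG cytosine and no CXG cytosine. By class, 370 belonged to adjacent CpG pairs, 468 to spaced CpG pairs and 251 had no listed partner. Of the 1090 selected sites, 850 were also in the site list, mostly at lower listed levels: 25.5% of adjacent-pair and 26.3% of spaced-pair cytosines with listed levels of 30 to 40% were in the table, against 0 of 854 adjacent-pair cytosines at 80 to 90% and 0 of 1125 at 90% or more. Among spaced-pair cytosines, 14 of 1033 at 70 to 80%, 1 of 905 at 80 to 90% and 0 of 68 at 90% or more were in the table. All 1090 selected sites were at least 33 points higher in some comparison, which a cytosine highly methylated in every medium cannot be. The few selected sites at high listed levels, and the lack of CXG sites, may therefore follow from the selection alone. CpG sites of the table were in gene bodies at 77.8%, other listed CpG sites at 79.1%, a difference that did not pass Fisher's exact test (two-sided p = 0.310). They touched the bodies of 662 genes, 111 of them with a symbol.

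At the selected sites methylation was lowest in replete cultures and highest in co-limited cultures. The mean level over the 1090 sites was 30.4% ± 1.51 (SD, n = 2) in replete, 46.7% ± 0.00684 (SD, n = 2) in iron-limited and 72.4% ± 0.00612 (SD, n = 2) in co-limited cultures. On the 882 sites above 0 in every library, the means were 37.5% ± 1.85, 52.9% ± 0.00738 and 78.0% ± 0.0258 (SD, n = 2 each). The iron-limited and co-limited means differed between replicates by 0.00967 and -0.00865 points, while single sites differed with SDs of 10.4 and 5.84 points. Whether replicates were scaled to each other is not given in the sources used here, so these 2 SDs are not taken as a spread between cultures. Each difference between media was larger than the replete SD, and each exact permutation test gave p = 0.3333, the smallest p that 2 against 2 libraries allow. The iron-limited mean lay between the others at 805 of the 882 sites, below the replete mean at 72 and above the co-limited mean at 5; selecting sites for a wide gap between the outer groups by itself favours such an order.

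After about 1 year of co-limitation, methylation was higher than in replete cultures at nearly every selected site, which the authors had chosen on these same libraries. In recQ, which encodes a DNA helicase of recombination and repair, the level at position 5007927 rose from 14.2% ± 5.95 to 94.3% ± 8.04 (SD, n = 2 each; limma adjusted p = 0.000328). The largest rise, 82.5 points, was at position 1695492 in Tery_1077, from 11.5% ± 1.40 to 94.0% ± 8.49 (limma adjusted p = 0.00144). The iron-limited libraries read 67.9% and 22.2% there, so replicates at this site could differ widely. At position 6617737 in Tery_4295 both co-limited libraries read 100% against 23.9% ± 1.55 in replete cultures, and Tery_2829 (position 4398176) rose by 72.5 points.

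In all, limma called 1044 of the 1090 sites, in 634 gene bodies, all with higher methylation in co-limited cultures. None was called lower, and none of the 1089 sites with an unadjusted p under 0.05 was lower. The median difference was 40.3 points (quartiles 36.1 and 45.9). The other 6 sites with the largest rises were listed at 0 in both replete libraries and lay in Tery_0843, Tery_2108, Tery_0657, Tery_3403, TERY_RS35995 and between genes at position 829013. Their co-limited means ran from 70.8% (TERY_RS35995) to 73.0% (Tery_0843). On the 882 sites above 0 in every library, 848 were called, all higher. With all 1090 sites, the count was 641 without co-limited replicate 1 and 640 without co-limited replicate 2.

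Among the genes of nitrogen fixation, 3 of the 6 genes with a listed site nearby carried a selected site, and all 3 were called higher in co-limited cultures. In nifX, a protein of nitrogenase cofactor assembly, the level at position 6388724 rose from 40.3% ± 1.76 to 74.7% ± 1.33 (SD, n = 2 each; limma adjusted p = 0.000286). The site at position 6378095 in nifS, the cysteine desulfurase that supplies sulfur for iron-sulfur clusters, was listed at 0 in both replete libraries and reached 47.2% ± 5.75. Within 100 bases of nifK, which encodes a nitrogenase subunit, the site at position 6385108 was also listed at 0 in replete cultures and reached 39.3% ± 0.207. The list did not stand out from all genes with listed sites, of which 23.1% had a selected site (Fisher's exact p = 0.140, adjusted over the lists 0.803).

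For the iron and phosphorus lists, 1 gene each was called. sufB, a scaffold protein for iron-sulfur cluster assembly, rose from 36.6% ± 11.6 to 71.0% ± 3.23 (limma adjusted p = 0.00176), and was the sole gene with a selected site among 5 of its list with listed sites. ppk1, the kinase that makes polyphosphate stores, rose from 26.5% ± 7.73 to 59.6% ± 2.56 (limma adjusted p = 0.000843), the sole such gene among 12. Of 13 photosystem genes with listed sites, psaB, a core protein of photosystem I, held 2 sites of a spaced pair, which rose from 50.7% ± 4.21 to 89.4% ± 2.501 and from 57.6% ± 2.85 to 94.2% ± 0.293.

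Of 21 ribosomal protein genes with listed sites, 5 carried a called site. rplE rose from 18.9% ± 6.54 to 74.98% ± 0.439 and rpsN from 35.4% ± 2.13 to 71.4% ± 0.0673; rplN and rplT rose by 41.2 and 38.9 points, and rpsH was listed at 0 in replete and reached 33.2% ± 0.998. The signal transduction and transcription list matched 2 symbols and so misses other regulators; its sole gene with a listed site, sigC, a sigma factor, rose from 54.5% ± 1.05 to 92.4% ± 5.70. No phycobilisome gene (2 with listed sites), gas vesicle gene (2), transposase gene (1) or toxin-antitoxin gene (1) carried a selected site, and the carbon fixation and DNA methylation lists had 0 genes with a matching symbol. For genes with a selected site among genes with any listed site, none of the 10 lists that could be tested passed Fisher's exact test (lowest adjusted p 0.803; 0 lists with an unadjusted p under 0.05). For called genes among genes with a selected site, none of the 6 lists passed (lowest adjusted p 1; 0 lists with an unadjusted p under 0.05), but since 95.8% of the 741 genes were called, no list of this size could have shown an excess. All 13 sites of the fixed lists were called with the p adjusted over the list alone as with the p adjusted over all sites; since the authors selected these sites on the same libraries, neither count is independent evidence.

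**Figure D2:**
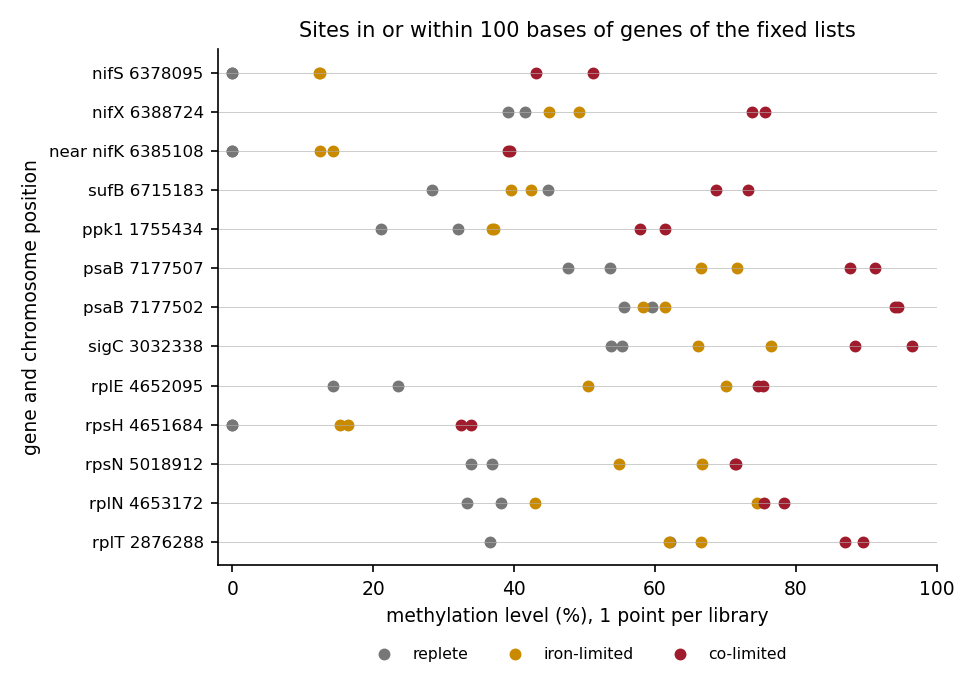
Methylation level (horizontal axis, percent) at each selected site in or within 100 bases of a gene of the fixed lists (vertical axis, gene and position), 1 point per library, coloured by medium. Co-limited libraries lie above both replete libraries at every one of the 13 sites, and nifS, rpsH and the site near nifK are listed at 0 in both replete libraries.

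In iron-limited cultures, 2 months after phosphate had been given back, methylation was higher than in replete cultures at 1012 of the 1090 selected sites. At these sites the rises were smaller: 63 sites were higher by at least 33 points, against 1056 in co-limited cultures. All 1090 sites had some pair of media at least 33 points apart, so the 1056 largely restates the selection. The contrast therefore holds for the selected sites alone. recQ rose from 14.2% ± 5.95 to 71.5% ± 3.15 (SD, n = 2 each; limma adjusted p = 0.00657). uvrC, a subunit of the nucleotide excision nuclease, rose at position 5124361 from 29.3% ± 10.0 to 77.0% ± 4.30 (limma adjusted p = 0.00128). ruvB, the motor of Holliday junction migration, was listed at 0 in both replete libraries and reached 45.5% ± 3.13. mnmA, a tRNA thiolation enzyme, rose from 23.5% ± 4.36 to 66.6% ± 2.41 at position 1174043. Other selected sites of these genes were not called: positions 1174240 and 1174817 in mnmA rose by 16.8 and 30.2 points, and position 5124296 in uvrC by 17.2 points. DNA repair and recombination genes, a list chosen after seeing the data, did not stand out in this comparison: 3 of 12 with a selected site were called, against 9 of all 111 genes with a symbol (Fisher's exact p = 0.0564, adjusted over 9 tests 0.169).

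limma called 52 of the 1090 sites in this comparison, in 38 gene bodies, all with higher methylation in iron-limited cultures. None was called lower, with 5 lower among the 691 sites at an unadjusted p under 0.05. The largest rise, 64.4 points, was in the pseudogene Tery_2481 at position 3821350, where replete replicate 1 read 19.4% and replicate 2 was listed at 0. The other 5 of the 10 largest rises lay between genes, at positions 3850188, 1104542, 2942798, 1534176 and 2318595, and ran from 42.8 to 52.6 points. The median difference over all sites was 17.0 points (quartiles 9.39 and 23.2), and 350 sites passed the adjusted p with no minimum difference.

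No site of the nitrogen fixation, iron or phosphorus lists was called in iron-limited cultures. nifX stood at 47.1% ± 3.06, sufB at 41.0% ± 2.00 and ppk1 at 37.0% ± 0.226, which were 6.79, 4.40 and 10.5 points above replete (limma adjusted p = 0.165, 0.537 and 0.1000). The nifS site and the site near nifK stood at 12.4% ± 0.0387 and 13.4% ± 1.39, from a listed 0; both passed the adjusted p but not the 33-point minimum. rplE was the sole called gene of any fixed list, at 60.3% ± 13.8 against 18.9% ± 6.54 in replete (limma adjusted p = 0.00549). rpsH, at 15.9% ± 0.795 from a listed 0, and rpsN, at 60.8% ± 8.32, also passed the adjusted p alone. Of the 13 sites of the fixed lists, 1 was called with the p adjusted over the list alone, as over all sites. None of the 6 lists that could be tested passed Fisher's exact test (lowest adjusted p 1, with 0 lists at an unadjusted p under 0.05). The iron, phosphorus, photosystem and signal transduction lists held 1 gene each with a selected site. With 46 of the 741 genes called, lists of that size could not have passed.

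The count of iron-limited calls depended on single libraries: it ranged from 25 to 73 with a library left out, with 73 (72 higher, 1 lower) without replete replicate 1, 27 without iron-limited replicate 2 and 25 without either co-limited replicate, and was 0 with the zeros set to 20% (555 sites at an unadjusted p under 0.05). On the 882 sites above 0 in every library it was 47, of which 1 was lower (position 421937 in TERY_RS34330), and it was 1, that same lower site, without replete replicate 1, 0 without replete replicate 2 (394 sites at an unadjusted p under 0.05) and 83 without iron-limited replicate 1.

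The iron-limited difference was larger at adjacent than at spaced CpG pairs, a contrast chosen after seeing the data. On sites above 0 in every library, the 358 sites in adjacent pairs averaged 38.5% ± 3.17 in replete, 60.3% ± 1.14 in iron-limited and 80.03% ± 0.244 in co-limited cultures (SD, n = 2 each). The 428 sites in spaced pairs averaged 38.8% ± 0.0293, 48.1% ± 1.57 and 78.4% ± 0.143. The median rise in iron-limited over replete cultures was 21.6 points in adjacent and 9.11 points in spaced pairs, a difference of 12.4 points (bootstrap 95% interval over sites 10.9 to 13.7). At the 95 such sites with no listed partner the median rise was 19.0 points (quartiles 13.1 and 24.2), nearer to adjacent pairs. That class may hold cytosines of either pair type whose partner was not listed, so it cannot show which pair class is the unusual one. For co-limited over replete cultures the medians were 40.3 and 38.5 points, a small difference of 1.75 points (bootstrap 95% interval over sites 0.841 to 2.84). The iron-limited cultures, made from the co-limited ones, stood below them by medians of 19.0 points in adjacent and 30.8 points in spaced pairs. Per library, the mean of adjacent minus spaced sites was 10.3 and 14.1 points in the iron-limited libraries, 1.84 and -2.60 in the replete libraries and 1.94 and 1.39 in the co-limited libraries (iron-limited against replete, exact permutation p = 0.3333, the smallest possible). The levels were lower in iron-limited than in replete cultures at 67 spaced-pair sites and at 3 adjacent-pair sites.

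**Figure D3:**
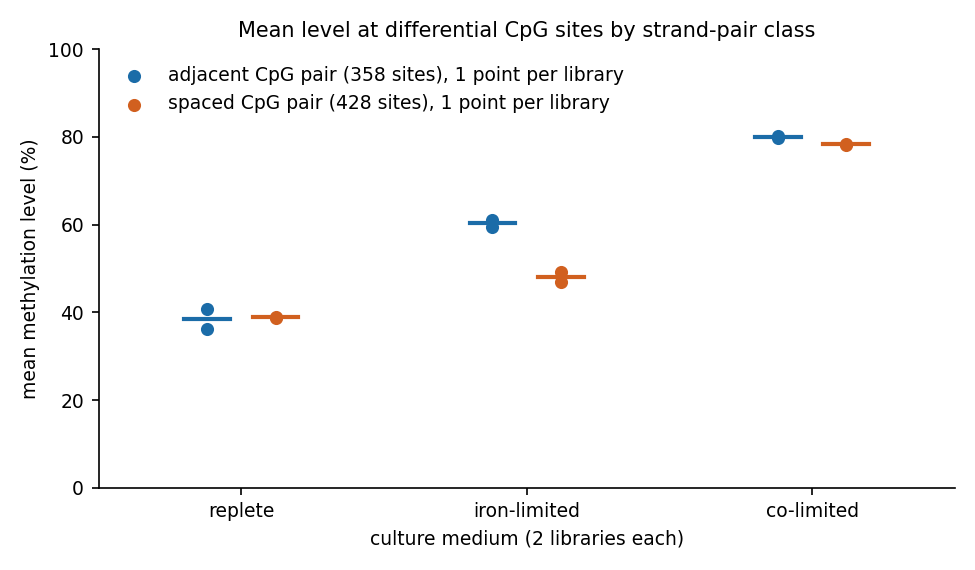
Mean methylation level (vertical axis, percent) at selected sites above 0 in every library, for adjacent and spaced CpG pairs in the 3 media (horizontal axis); points are libraries and short lines are group means. The classes lie together in replete and co-limited cultures and apart in iron-limited cultures, at 60.3% and 48.1%.

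**Figure D4:**
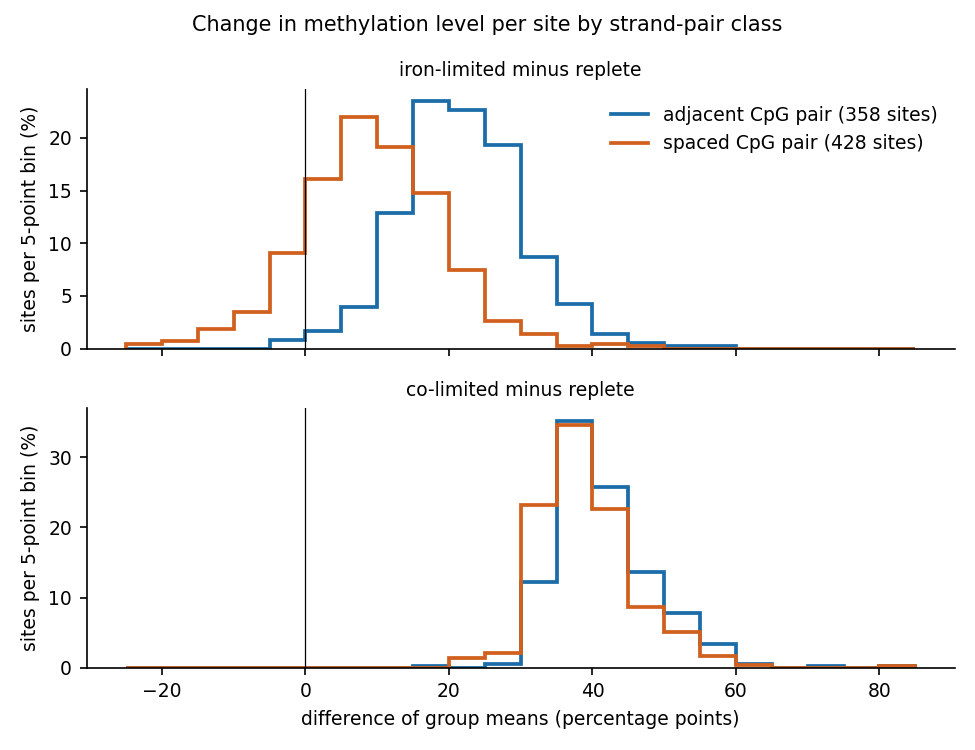
Share of sites (vertical axis, percent of the class) by the difference of group means (horizontal axis, percentage points, 5-point bins) for iron-limited minus replete (top) and co-limited minus replete (bottom), 1 line per class. The medians are 21.6 and 9.11 points at the top and 40.3 and 38.5 points at the bottom.

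Co-limited cultures also stood above iron-limited cultures, the comparison in which phosphate supply and the time since its return differ while iron is the same. Position 6617737 in Tery_4295 showed the largest difference, with 100% in both co-limited libraries, 16.7% in iron-limited replicate 2 and a listed 0 in replicate 1. Tery_1848 (position 2831688) was listed at 0 in all 4 other libraries and read 58.6% ± 2.02 (SD, n = 2) in co-limited cultures (limma adjusted p = 0.000433). Tery_4787 stood at 22.4% ± 8.10 in iron-limited and 80.4% ± 6.17 in co-limited cultures, Tery_0322 at 21.5% ± 10.5 and 76.5% ± 5.12, and Tery_3822 at 30.1% ± 7.51 and 83.9% ± 2.04 (limma adjusted p = 0.00144 for each).

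limma called 249 sites, in 172 gene bodies, all higher in co-limited cultures; none was called lower, with 1 lower among the 968 sites at an unadjusted p under 0.05. The median difference was 25.01 points (quartiles 18.7 and 32.8). By class, 170 called sites were in spaced pairs and 31 in adjacent pairs. The remaining sites among the 10 largest rises lay between genes, at positions 829013, 1766054, 7437201, 2329587 and 4994710, with rises of 66.0, 58.0, 53.8, 52.1 and 52.1 points. Of the nitrogen fixation list, nifS was called, with 12.4% ± 0.0387 in iron-limited and 47.2% ± 5.75 in co-limited cultures (limma adjusted p = 0.00144). No site of the iron or phosphorus lists was called, and none of the 6 lists tested passed Fisher's exact test (lowest adjusted p 0.996, with 0 lists at an unadjusted p under 0.05). The iron, phosphorus, photosystem and signal transduction lists, with 1 gene each, could not have passed, since 26.7% of the 741 genes were called. With the p adjusted over the list alone, 2 of the 13 sites of the fixed lists were called, as over all sites: the nifS site and the psaB site at position 7177502.

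This count fell to 0 without either co-limited replicate, where the lowest limma adjusted p was 0.0139 and 0.0143, with 793 and 805 sites at an unadjusted p under 0.05, and to 143 without iron-limited replicate 2. On the 882 sites above 0 in every library, 212 sites were called and between 187 and 255 with a library left out.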

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

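Leaving aside 5 alternatives whose outcome was fixed and 7 gene-list alternatives that stayed at 0 lists, 73 alternative values stayed within 1.5 times the reported count or within the spread of the reported value and 24 did not. A count within 1.5 times of the reported one need not hold the same sites. Without iron-limited replicate 1, the sites called for iron-limited against replete were partly other sites. No mean difference turned its direction. The direction of 1 count turned: on the 882 sites above 0 in every library, iron-limited against replete went from 46 higher and 1 lower to 0 higher and 1 lower without replete replicate 1. Sites above 0 in every library, zeros set to 20% and the tests on those subsets were chosen after seeing the data. With a minimum difference of 25 points, limma called 165 sites for iron-limited against replete and 500 for co-limited against iron-limited cultures. With no minimum difference the counts were 350 and 737, and on the 882 sites above 0 in every library 172 (171 higher, 1 lower) and 626. Only the 4 libraries compared gave 25 calls for iron-limited against replete, and zeros set to 20% gave 0 (555 sites at an unadjusted p under 0.05, lowest adjusted p 0.0150). With each library left out in turn, the counts ran from 25 to 73 for iron-limited against replete (25 without either co-limited replicate), from 640 to 1014 for co-limited against replete (641 and 640 without co-limited replicates 1 and 2), and from 0 to 258 for co-limited against iron-limited (143 without iron-limited replicate 2). The 0 calls, without either co-limited replicate, came with lowest adjusted p of 0.0139 and 0.0143, just over the threshold. On the sites above 0 in every library the counts ran from 0 to 83 (0 without replete replicate 2, 1, a lower site, without replete replicate 1, 83 without iron-limited replicate 1), 685 to 848 and 187 to 255. A group left with a single library was assumed to vary like the others. The cause of these changes was not tested, beyond the fewer libraries themselves and limma's prior degrees of freedom, 2.80 on all sites and 15.4 on the 882 sites. The replicate block gave 46, 1042 and 253 calls for the 3 comparisons and stayed within 1.5 times of every count, also on the 882 sites (39, 848 and 212). Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0344, 0.0114 and 0.00127. The mean difference was 40.5 points for co-limited against replete and 25.1 for co-limited against iron-limited on sites above 0 in every library, and 27.6 for the latter as a median over sites; the cause was not tested. The share of listed sites outside genes but nearby was 12.8% with windows of 300 bases, by construction, and CpG made up 69.4% of sites listed at 50% or more. Coverage minimums of 5 and 20, pooled Fisher's exact tests and coverage-weighted means were not run, since the tables give fractions only. Leaving out sites that vary by under 10 points removed no site, and lists tested where nearly every gene was called could show no excess, so these 5 alternatives say nothing about stability. The unknown depth limits every level printed.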

Other observations

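All gene lists, named genes, tests and explanations in this part were chosen after the results were seen. Of 25 DNA repair and recombination genes with a listed or selected site, 12 carried a selected site, against 21.6% of all 515 genes with a symbol (Fisher's exact p = 0.00236, adjusted over 9 tests 0.0212). The 3 added lists were drawn up after seeing which genes carried selected sites, so their p values restate what prompted them and are not independent evidence. They were recQ, ruvB, uvrC, recF, recG, recR, mutL, sbcC, sbcD, ligA, priA and xth. All 25 genes of the list held a median of 6 listed or selected positions, against 4 for all genes with a symbol. Random draws of genes matched on that number held 7.12 on average (permutation p = 0.0428, adjusted over the lists 0.0642), so the excess did not pass the adjusted test. In sbcD, a nuclease subunit, methylation went from 22.5% ± 0.151 in replete and 37.8% ± 3.28 in iron-limited to 86.2% ± 3.67 in co-limited cultures (SD, n = 2 each).

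Genes of protein folding and turnover carried selected sites at 12 of 29 genes (Fisher's exact p = 0.0172, adjusted 0.0775; matched on positions, 6.08 expected, p = 0.0134, adjusted 0.0402). The protease gene ctpB held 4 such sites, with co-limited means from 64.0% to 91.2%; the chaperone genes groL and dnaK rose by 35.9 and 40.6 points in co-limited over replete cultures. Central carbon genes, with 7 of 23, did not stand apart (Fisher's exact p = 0.301). ntcA, the global regulator of nitrogen use in cyanobacteria, read 43.6% ± 2.05 in replete, 69.9% ± 8.10 in iron-limited and 87.4% ± 0.827 in co-limited cultures. ltrA, a gene of group II intron mobility, read 38.2% ± 3.17, 61.8% ± 8.09 and 80.9% ± 1.76 in the same order.

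The genes with the most selected sites were Tery_2481, Tery_3923 and Tery_4989, in which listed positions recur at repeating distances. Tery_2481 and Tery_3923 had 11 each and Tery_4989 had 10, where random draws of as many sites gave a median highest count of 6. Among their listed or selected positions, the most frequent distance was 276 bases in Tery_2481 (12 pairs), 123 in Tery_3923 (20 pairs) and 93 in Tery_4989 (17 pairs), and 2000 random placements gave at most 6, 6 and 7 pairs. Among the selected sites alone, 23 of 54, 14 of 54 and 9 of 43 pairs lay within 1 base of a multiple of that distance, which was not compared with random placements. Genes with at least 3 selected sites numbered 23, against a median of 27 in random draws (permutation p = 0.857).

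Some values stand out without a test. Among the 4 CHH sites of the table, 3 lay within 10 bases of each other in Tery_2634 and were listed at 0 in all replete and iron-limited libraries, and at 42.2% and 42.1% in the co-limited libraries for positions 4082732 and 4082737. The mean over the 1090 sites differed between replicates by 0.00967 points in iron-limited and -0.00865 points in co-limited cultures, against 2.14 points in replete cultures, although single sites differed with SDs of 10.4, 5.84 and 9.43 points. At position 6617737 in Tery_4295, iron-limited replicate 1 was listed at 0 and both co-limited libraries at 100%.

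The exact zeros form a block of their own. At 206 sites both replete libraries were listed at 0, and at 1 site only replete replicate 2 was, while at these 206 sites the iron-limited medians were 19.4% and 19.5% and the co-limited medians 46.7% and 46.1%. If zeros were measured low levels, low values beside them would be expected, yet 413 replete values at 0 stood beside 0 values between 0 and 5% (the lowest above 0 was 7.41%), against 12 and 8 in the iron-limited libraries (Fisher's exact p = 4.39e-12). This is what zeros that stand in for sites without a value, or for values under a minimum, may look like. Of the 206 sites, 25 were in the site list. Values missing whatever the level would also have brought in highly methylated sites. Yet no co-limited value at the 206 sites exceeded 75.3%, against a median of 84.4% over the site list, whose libraries are not given. This argues against values missing whatever the level, but not against values under a minimum. A minimum set on each library alone would leave sites at 0 in a single replete library. Only 1 such site stood beside the 206, although replete replicates differed with an SD of 10.4 points at the 882 sites above 0. This argues against a minimum of that kind, but not against a minimum set on both replete libraries together. Sites truly unmethylated in replete cultures, the biological explanation for all 206, cannot be told apart from values under such a shared minimum because no depth is held here. Differences at these sites are therefore at most as firm as the listed 0.

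The larger iron-limited rise at adjacent than at spaced CpG pairs held against each technical explanation tested. Selection of sites with low replete values would bias both classes by about the replicate spread, which differed little between them (5.05 and 4.98 points), and the class difference was 12.4 points (permutation over sites p = 0.0001, the smallest that 10000 permutations can give). That p covers the spread over sites of the same libraries, not over cultures. Over libraries the exact permutation p was 0.3333, the smallest possible. Different replete levels are argued against by a mean difference within bins of replete level, weighted by sites per bin, of 12.2 points (from 6.53 to 13.9 points in the 4 bins). Sites chosen for a low iron-limited level are argued against by 11.7 points on sites at least 33 points higher in co-limited than in replete cultures. The mean iron-limited rise over replete was 52.6% of the co-limited rise at adjacent and 23.4% at spaced pairs. The iron-limited cultures were made from the co-limited ones, and there was no time course. A response of the classes to the media, the biological explanation, and a difference between these particular cultures were not tested and stay open.

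No selected site was lower in co-limited than in replete cultures by 33 points, and 1056 were higher by as much. Incomplete bisulfite conversion at 1 failure rate leaves no level below that rate, apart from noise. At the 206 sites listed at 0 in replete cultures the lowest co-limited mean was 33.1%. Their lower quartile, 40.5%, was taken as the cap, which allows a higher rate than the lowest mean would. With that rate, 571 of the 882 sites above 0 in every library stood over 3 SD above the level allowed. Because sites were selected for a rise, chance was counted over all 15892 listed or selected positions. It gives 21.5 if deviations are normally distributed, and heavier tails were not tested. The excess argues against a single rate as the whole cause. The rates needed at different replete levels (56.1% at 20 to 30% and 78.9% at 50 to 60%) decide nothing, since the 33-point minimum for selection by itself makes them differ. That only rises were kept when the table was made cannot be told apart from a gain of methylation, since the sites that were not selected are not analysed here: only 1 site, position 421937 in TERY_RS34330, was lower by 33 points in any comparison (by -38.3 points in iron-limited against replete cultures, with replete libraries at 57.3% and 100%), and it was also over 33 points higher in co-limited than in iron-limited cultures. A gain of methylation under co-limitation, the biological explanation, stays open beside that choice of sites.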
